A study of Bos taurus with 36 samples.

How the data were processed

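RNA from liver, peripheral blood granulocytes and peripheral blood mononuclear cells of Holstein cows was measured on a 1-colour Agilent bovine array with 15208 non-control probes and 536 control spots. The 36 arrays make 9 groups of 4, which are 3 tissues in the estrous cycle 1st, the estrous cycle 2nd and pregnancy. The labels do not define 1st and 2nd. Per the labels, the pregnant cows numbered 1 to 4 were at day 150, 150, 165 and 162 of gestation. The series text gives 4 cows in the estrous cycle and 4 in mid gestation, so the 8 estrous cycle arrays of a tissue were taken to come from 4 cows. The extraction label of the samples speaks of endometrial tissues, whereas the sample labels name liver and blood cells; the sample labels were used.

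Per the file headers, the authors extracted the scans with Agilent Feature Extraction 9.5, and the deposited array files hold spot signals as intensity, background-subtracted and spatially detrended but not scaled between arrays. The deposited value table is in log2. It was checked against the array files and differed from log2 of the processed signal minus each array's 75th percentile by at most 0.0159. The main values were computed again from the array files as log2 of the processed signal minus the 75th percentile of the array, with spots marked as outliers left out. The 75th percentile of the signal ran from 934 to 5900 between arrays, and 10079 to 13012 probes per array were well above background. The number of arrays limits the precision, and an array has no counting depth.

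Probes were named from the accession, gene identifier, symbol, synonym or human homolog in the files, against the genes of the bovine reference annotation. This named 7100 probes and 6767 genes, and 8108 probes stayed unnamed. These were tested as features but are not named in the text. For the 227 genes with more than 1 probe, the brightest probe was kept, which left 14875 features, called genes below. The arrays carry no coordinates, so no positions are given. A feature was tested where it was well above background on at least 3 of the 4 arrays of at least 1 group compared.

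Fits used limma 3.58.1 in R 4.3.3, with lmFit, eBayes and two-sided moderated tests, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. For pregnant against estrous cycle, the 1st and 2nd arrays of a number were averaged, giving 4 values against 4. For 2nd against 1st, 4 arrays were compared with 4. For granulocytes against mononuclear cells, 8 values were compared with 8, with pregnancy as a covariate. A difference between tissues in the pregnancy effect was tested as an interaction. Changes are log2 differences with their standard error from limma, and each fold change is 2 to that power. Where no array of a group was well above background, the fold was computed against the group's limit and is written as at least that fold.

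Whether equal numbers pair samples was checked from the correlation, across genes, of the deviations from the group mean. Equal numbers correlated above 0.1 at all 4 numbers between the 1st and 2nd liver arrays, with a lowest r of 0.260. They did so between the animal values of granulocytes and mononuclear cells too, with a lowest r of 0.168 in pregnancy and 0.259 in the estrous cycle. In pregnancy the highest r between different numbers was larger, at 0.219. Over single arrays of the 1st and the 2nd, these fractions did not pass, with a lowest r of 0.0608 and -0.0245. Nor did liver with granulocytes, at 0.0453 and 0.0632. Over animal values, liver correlated above 0.1 at all 4 numbers in the estrous cycle, with a lowest r of 0.195 with granulocytes and 0.303 with mononuclear cells. In pregnancy the lowest were 0.0720 and 0.0961, so liver passed this rule with the blood fractions in the estrous cycle only. These 2 values still lay above the highest r between different numbers, 0.0590 and 0.0431. Pairing in pregnancy is thus not argued against. Between the 1st and 2nd arrays of granulocytes and of mononuclear cells the lowest r was -0.158 and -0.181, and between cycling and pregnant animals no tissue passed. These numbers were therefore not used as pairs in the main fits. The averaging of the 1st and 2nd arrays of a number still takes equal numbers as 1 cow. The check did not bear this out in the 2 blood fractions, and counts over single arrays are given below.

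The arrays lay on 8 slides. Slide 1 held the 4 liver 1st arrays, slide 3 the 4 liver 2nd and 4 granulocyte 2nd arrays, and slides 2 and 5 the pregnant liver arrays. Slide 4 held the 4 pregnant granulocyte arrays and granulocyte 1st arrays 1 and 2, and slide 6 granulocyte 1st arrays 3 and 4 and mononuclear pregnant array 1. Slide 7 held mononuclear pregnant arrays 2 to 4, all 4 mononuclear 1st arrays and 2nd array 1, and slide 8 the other mononuclear 2nd arrays.

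Before the data were examined, 38 gene lists of metabolic pathways, stress responses, immune functions and cell type markers were fixed. Lists of at least 5 tested genes were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Fry, another set test, was run beside it. A list is said to pass or not by camera unless fry is named. The named genes were chosen by a rule fixed at the same time. It takes, among named genes past the threshold whose groups do not overlap over single arrays, the 10 with the largest rise and the 10 with the largest fall. From each list that passes or has at least 3 members past the threshold, it adds up to 4 members with the smallest adjusted p. The text names part of these. Of the genes first picked for the text, 26 choices over the comparisons were left unnamed after the alternatives had been run, most of them because their calls moved, so the genes named are steadier than the rule alone would give. Then 6 genes past the threshold in all 3 tissues, the eosinophil markers and ACTC1 were added. The alternatives were run on 24 of the left-out choices as well, and their values are given apart from those of the named genes. Genes that passed in all 3 tissues were also looked up after the results were seen. The alternatives tried were normexp background correction with an offset of 50, quantile normalization, the authors' values, no filter and a stricter filter, the mean over probes, an intensity trend, a block by number, a block by slide, single slides, each estrous group alone, single arrays, and leaving out each array in turn. The same splits of the arrays into groups were counted, at most 100 for a result.

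The fits were tested on simulated data with the means and spreads of the real genes and 200 changed genes. Of the changes of 1 log2, 65% were recovered in liver, 43% in granulocytes and 45% in mononuclear cells for pregnant against estrous cycle, and of those of 2 log2, 97%, 83% and 89%. For 2nd against 1st the shares were 72%, 28% and 56% at 1 log2. The share of false calls in the 10 simulated comparisons was between 3.51% and 10.0%. The simulated genes and arrays were drawn independently, without slide effects, correlation between genes or animals shared between tissues. Fewer genes changed than passed in the real pregnancy comparisons. These shares hold for such data and need not hold for the real arrays.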

Results

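Gene expression was measured on 36 arrays, 4 in each of 9 groups, from liver, granulocytes and mononuclear cells of cows in the estrous cycle 1st, the estrous cycle 2nd and mid gestation. The title of the series relates granulocyte profiles to liver function. Between 66.3% and 85.6% of the probes of an array were well above background. All changes below are log2 differences ± SE between 4 pregnant and 4 cycling animals unless another n is given, and the p-values are adjusted over all genes tested in the comparison. The largest changes given are those among named genes whose group values did not overlap.

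The first comparison asked how liver expression in mid gestation differed from that in the estrous cycle. In the liver of pregnant cows the largest rise was that of NOCT, a circadian deadenylase-like enzyme, which was 20.4-fold higher (4.35 ± 0.48, adjusted p = 0.00127). IGFBP1, a liver-secreted binding protein of insulin-like growth factors, was 6.76-fold higher (2.76 ± 0.33, adjusted p = 0.00171). HDC, which makes histamine, rose by 3.17 ± 0.32. The immediate-early genes DUSP1 (3.21 ± 0.76) and GADD45B (3.07 ± 0.67) rose too. Of 4 transcripts known as products of the placenta, 3 rose, over all genes and adjusted over the list alone: PAG7 was at least 3.11-fold, CSH2 at least 2.19-fold and PAG5 at least 1.62-fold higher. These 3 were above background in pregnant cows only, whereas TKDP3 was so in all cows and did not pass (-0.05 ± 0.35). Of 27 such genes on the array only 4 were tested, and these 3 passed the filter through the pregnant group alone. That 3 of 4 rose is thus partly set by the filter. Pregnant liver arrays also had more probes well above background, 11563 to 12327 against 10276 to 11487 in the estrous cycle. Among the falls were BHLHE41, a circadian repressor (-2.06 ± 0.23), the histone gene H2BC19 (-2.05 ± 0.30), PALMD (-1.92 ± 0.20) and CYP2U1 (at least 1.95-fold lower). The values of the 4 pregnant and the 4 cycling cows did not overlap for any gene named here as higher or lower.

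Genes of glucose production were among those that rose. Of 19 genes of gluconeogenesis, 6 rose, 1 fell and 12 did not pass, and 7 rose and 1 fell adjusted over the list alone. PCK1, the entry enzyme of the pathway, rose by 0.59 ± 0.09, TAT by 0.84 ± 0.15 and LDHA by 0.79 ± 0.15, whereas MDH1 fell by 0.70. The list as a whole did not pass camera (adjusted p = 0.22608; 0.940 with an estimated correlation) but passed fry (adjusted p = 0.00846). Of 19 genes of fatty acid oxidation and ketogenesis, 3 rose and 1 fell, with the same counts adjusted over the list alone. ANGPTL4 rose by 1.90 ± 0.29. Of 16 genes of the urea cycle and amino acid catabolism, 5 rose and 2 fell, and 5 rose and 3 fell adjusted over the list alone. OTC rose by 0.64 ± 0.11 and GLUD1 was at -1.20 ± 0.21. Neither of these lists passed as a whole, with adjusted p of 0.69544 and 0.82859.

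Antioxidant genes were the only list that passed camera in liver, among the 32 tested there. Of 20 members 6 fell, none rose and 14 did not pass, and 7 fell adjusted over the list alone (median -0.38, adjusted p = 0.0005331). The call was lost with an estimated correlation (adjusted p = 0.920) and without the filter (adjusted p = 0.06264). Examples are NFE2L2, the regulator of the antioxidant response (-0.52 ± 0.08), PRDX1 (-0.68 ± 0.11), PRDX2 (-0.54 ± 0.10) and TXNRD1 (-0.57 ± 0.11). Some muscle genes moved in the same samples: ACTC1 rose by 1.35 ± 0.11 (adjusted p = 0.0007746), whereas ACTA1 was at least 80-fold lower in pregnant cows, TNNC1 was at -4.53 ± 0.75, MYOZ2 was at least 1.96-fold lower and PGAM2 was at -1.98 ± 0.44. The ACTA1 level ranged from -6.01 to 3.29 between estrous cycle arrays and from -9.77 to -7.75 between pregnant ones.

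**Figure D1:**
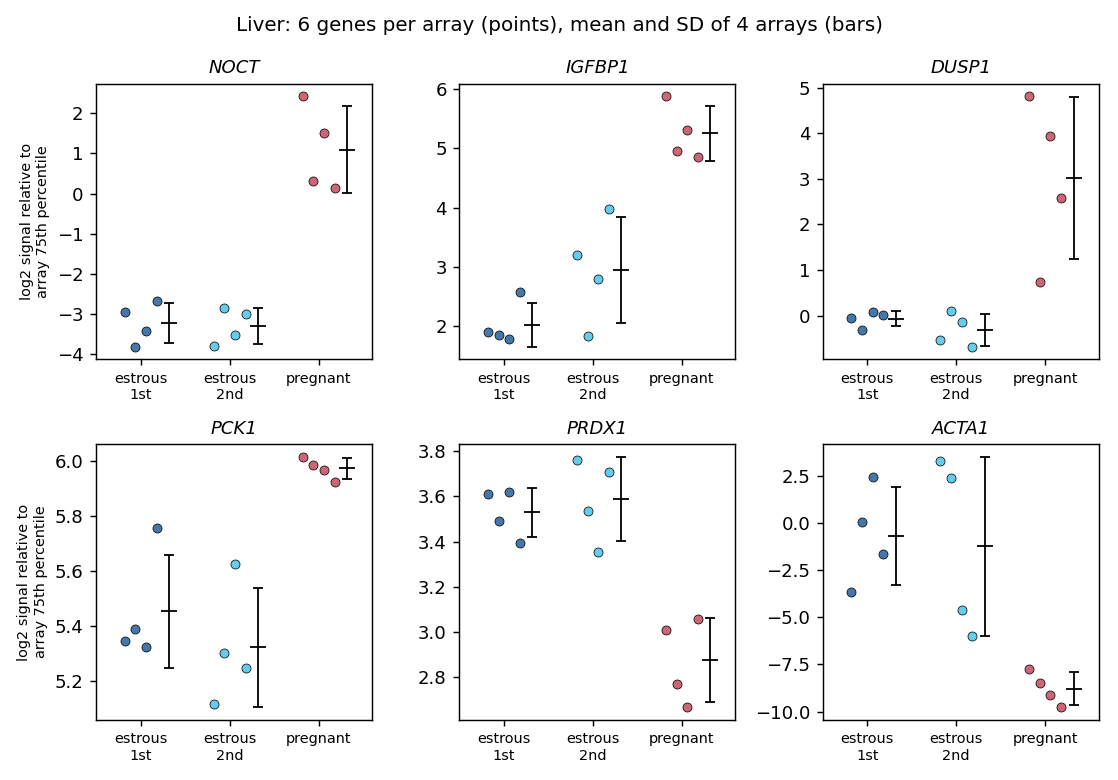
Each panel plots 1 gene in liver, with the log2 signal relative to the array's 75th percentile on the y axis, the 3 groups on the x axis, a point per array and the mean with SD of 4 arrays as a bar. NOCT, IGFBP1, DUSP1 and PCK1 lay higher and PRDX1 and ACTA1 lower in the 4 pregnant cows, and ACTA1 ranged from -6.01 to 3.29 between estrous cycle arrays.

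In all, 3073 of 11424 genes passed in liver, 1827 higher and 1246 lower in pregnancy, and 555 of them by more than 2-fold. The values of the 4 and 4 animals did not overlap for 30.5% of the genes tested, against 2.86% by chance. No slide held both groups, so a within-slide value could not be had, and state and slide cannot be told apart. Over the 12 single arrays 3207 genes passed with slide as a random block and 3843 without it. Such a block does not remove a difference between the slides of the 2 groups. Without the filter 4838 genes passed, of which 2902 were lower, so the majority turned. TNNC1 missed the threshold without estrous cycle 1st array 3 (adjusted p = 0.05501), and TNNC1 and PGAM2 missed it with slide as a random block.

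The same question was asked of granulocytes, the blood fraction rich in neutrophils. The largest rise in pregnancy was that of IGF1, the growth factor (21.4-fold, 4.42 ± 0.53, adjusted p = 0.00297). This fold is against the mean of the 1st and 2nd, between which IGF1 was not level. The 2nd minus the 1st was -2.05 without 1st array 1 and -2.95 without 1st array 4 (limma adjusted p = 0.06325 and 0.0664). FMOD, a collagen-binding proteoglycan, rose by 4.24 ± 0.71, the casein gene CSN1S2 by 4.23 ± 0.57, KLHL10 by 4.04 ± 0.54 and OPCML by 3.11 ± 0.33. H2BC12, a histone gene, rose by 3.54 ± 0.59, the kinase gene NUAK1 by 3.15 ± 0.64 and PPP2R2C, a phosphatase subunit, by 2.27 ± 0.36. The largest fall was that of CXCL2, a neutrophil-attracting chemokine (9.19-fold lower, -3.20 ± 0.53, adjusted p = 0.00674). SOCS2, a feedback inhibitor of growth hormone signalling, was at -3.06 ± 0.36, the nuclear receptor gene NR4A2 at -2.88 ± 0.46, FST at -2.59 ± 0.32 and the clock gene PER3 at -2.54 ± 0.39. WNT5A was at least 4.33-fold and SEMA3G at least 2.22-fold lower. The values of the groups did not overlap for these genes.

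Some inflammatory genes fell in granulocytes of pregnant cows. Of 25 inflammatory cytokines and NF-kB targets 7 fell, none rose and 18 did not pass, and 9 fell adjusted over the list alone (median -0.82, adjusted p = 2.237e-06). This call was lost with an estimated correlation (adjusted p = 0.712). CXCL8, the main neutrophil chemokine, was at -1.93 ± 0.31, and CCL2 was at least 2.04-fold lower. Of 20 interferon-stimulated genes 3 fell, none rose and 17 did not pass (median -0.60, adjusted p = 0.00837; 0.712 with an estimated correlation), and 4 fell and 1 rose adjusted over the list alone. The interferon call was also lost against the estrous cycle 2nd alone (adjusted p = 0.08843). The growth hormone and IGF axis had 2 members higher and 3 lower of 11 (adjusted p = 0.88315), and 3 higher and 3 lower adjusted over the list alone.

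Lymphocyte genes moved in the granulocyte fraction in the same samples. Of 12 T cell markers 6 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone (median -0.81, adjusted p = 0.00695). This call was lost with an estimated correlation (adjusted p = 0.712). CD3E was at -1.32 ± 0.25, CD3G at -1.50 ± 0.24 and CD163L1, a gamma delta T cell gene, at -1.93 ± 0.26. Of 8 B cell markers 4 rose, none fell, and 5 rose adjusted over the list alone, among them MS4A1 (1.41 ± 0.18) and POU2AF1 (1.57 ± 0.32). The B cell list did not pass as a whole (adjusted p = 0.15036). Of 10 MHC class II genes 4 rose and none fell, with the same counts adjusted over the list alone (median 0.97, adjusted p = 0.01866), among them BOLA-DOB (1.45 ± 0.28) and BOLA-DRA (1.11 ± 0.20). The class II call was lost with an estimated correlation (adjusted p = 0.712). Within slide 4, with 2 cycling animals, the T cell median was -0.58 and the call was lost (adjusted p = 0.38869), as it was with slide as a fixed block (adjusted p = 0.30737). The class II call was lost without the filter (adjusted p = 0.09451) and against the estrous cycle 2nd alone (adjusted p = 0.14022). BOLA-DRA missed the threshold without estrous cycle 1st array 1 (adjusted p = 0.07747). Between the fractions, the median level difference of T cell markers was -0.05 and that of B cell markers -0.34, granulocytes minus mononuclear cells.

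**Figure D2:**
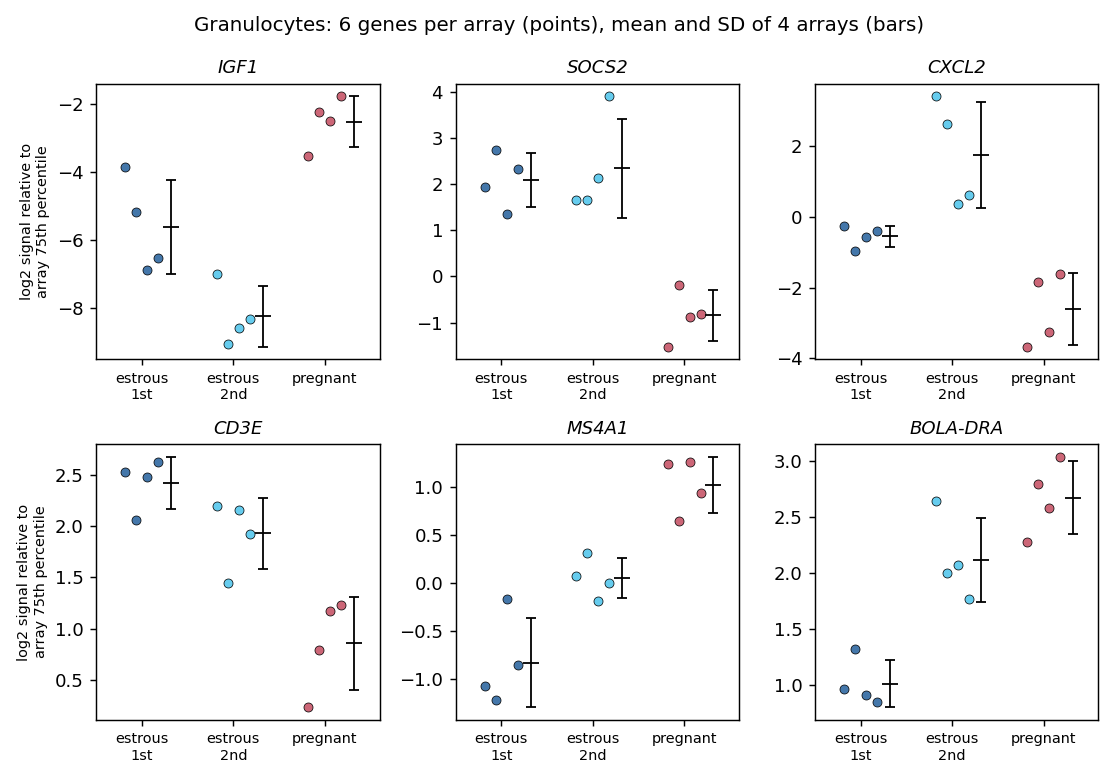
Each panel plots 1 gene in granulocytes, with the log2 signal relative to the array's 75th percentile on the y axis, the 3 groups on the x axis, a point per array and the mean with SD of 4 arrays as a bar. IGF1, MS4A1 and BOLA-DRA had higher and SOCS2, CXCL2 and CD3E lower means in the 4 pregnant cows.

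In all, 1969 of 11128 genes passed in granulocytes, 1173 higher and 796 lower, and 1062 by more than 2-fold. The values of the 4 and 4 animals did not overlap for 24.5% of genes, against 2.86% by chance. Within slide 4, which held 4 pregnant and 2 cycling animals, 1358 genes passed, and with slide as a fixed block over the 12 single arrays 1965. Against the estrous cycle 1st alone 733 passed, of which 465 were lower, and against the 2nd alone 2786, of which 1980 were higher. Over the 12 single arrays 1227 passed, of which 645 were lower. With normexp correction 836 of 1548 were lower, so that the majority turned in these 2 and against the 1st alone. IGF1, OPCML, CXCL2 and POU2AF1 missed the threshold within slide 4. FMOD, OPCML, CXCL2, CCL2 and POU2AF1 missed it with slide as a fixed block, and KLHL10, NUAK1 and POU2AF1 with normexp correction. The count was 1008 without pregnant array 3, 1030 without pregnant array 1, and 1079, 1137 and 1053 without estrous cycle 2nd arrays 1, 3 and 4. Without 2nd arrays 1 and 4 the majority turned as well, with 558 and 534 lower.

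In mononuclear cells, the fraction of lymphocytes and monocytes, the 3 largest falls in pregnancy were those of chemokine genes. CXCL2 was 124-fold lower (-6.95 ± 0.93, adjusted p = 0.00586), CXCL3 was at -5.64 ± 0.87, GRO1 at -5.38 ± 0.78 and CXCL8 at -4.37 ± 0.81. The chemokine receptor gene CXCR1 was at -4.52 ± 0.82, the defensin gene DEFB4A at -4.05 ± 0.68, and SDS at -4.26 ± 0.62. The hemoglobin genes HBE4 (-4.55 ± 0.60) and HBG (-4.36 ± 0.55) fell too. The largest rise was that of H2BC12 (18.2-fold, 4.18 ± 0.73, adjusted p = 0.01001). KCNMA1, a potassium channel gene, rose by 3.57 ± 0.74, NUAK1 by 3.32 ± 0.91, EXTL1 by 3.16 ± 0.51, CDKL4 by 2.85 ± 0.50 and PPP2R2C by 2.82 ± 0.26, and CLCA3 was at least 4.25-fold higher. The values of the groups did not overlap for these genes.

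Part of the inflammatory and myeloid genes fell in mononuclear cells. Of 25 inflammatory cytokines and NF-kB targets 16 fell and 1 rose, and 18 fell and 1 rose adjusted over the list alone (median -1.67, adjusted p = 5.8e-07). This call was lost with an estimated correlation (adjusted p = 0.272). Of 9 glucocorticoid-responsive genes 5 fell, none rose, and 8 fell adjusted over the list alone (adjusted p = 0.000102; 0.272 with an estimated correlation), among them ANXA1 (-2.78 ± 0.44) and DUSP1 (-2.98 ± 0.48). Of 14 neutrophil markers 5 fell, with 5 also adjusted over the list alone (adjusted p = 0.0006753; 0.310 with an estimated correlation), among them S100A12 (-3.19 ± 0.29), S100A8 (-2.96 ± 0.29) and TREM1 (-2.88 ± 0.28). Of 14 granule and antimicrobial genes 7 fell, and 9 adjusted over the list alone (adjusted p = 0.000102; 0.272 with an estimated correlation). Of 12 monocyte and macrophage markers 5 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.00712; 0.373 with an estimated correlation), among them CD14, the lipopolysaccharide co-receptor (-2.96 ± 0.27), and VCAN (-3.61 ± 0.34). TLR4 was at -2.52 ± 0.33. All 4 platelet markers fell, among them THBS1 (-3.02 ± 0.45), over too few genes for a set test. None of these list calls held with an estimated correlation. The medians of the neutrophil and monocyte lists were -0.42 and -0.90.

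Lymphocyte genes were counted in the same way in mononuclear cells. Of 13 T cell markers 9 fell and 1 rose, and 11 fell and 1 rose adjusted over the list alone (median -1.35, adjusted p = 0.000102; adjusted p = 0.272 with an estimated correlation, where the call was lost). CD3E was at -1.78 ± 0.28, CD3G at -1.48 ± 0.29 and the costimulatory receptor gene CD28 at -2.22 ± 0.30. Of 8 B cell markers 4 rose and none fell, and 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.0859, not passed), among them MS4A1 (1.67 ± 0.25) and IGHM (1.12 ± 0.23). The B cell list did pass fry (adjusted p = 0.00225). Of 11 MHC class II genes 3 rose and none fell, and 5 rose adjusted over the list alone (adjusted p = 0.03846), among them BOLA-DOB (1.54 ± 0.28) and BOLA-DRA (0.99 ± 0.21). The class II call was lost with an estimated correlation (adjusted p = 0.272) and with quantile normalization (adjusted p = 0.14127). Some neutrophil, platelet and monocyte markers were lower in the same samples, as given above.

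**Figure D3:**
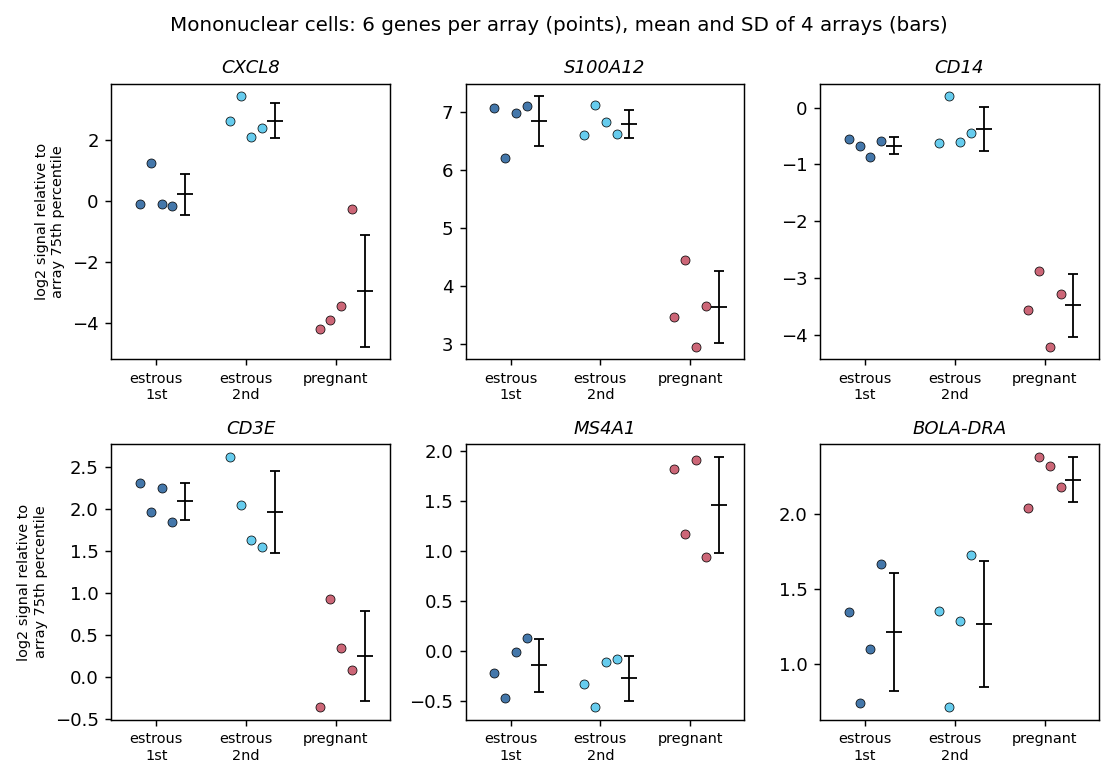
Each panel plots 1 gene in mononuclear cells, with the log2 signal relative to the array's 75th percentile on the y axis, the 3 groups on the x axis, a point per array and the mean with SD of 4 arrays as a bar. CXCL8, S100A12, CD14 and CD3E lay lower and MS4A1 and BOLA-DRA had higher means in the 4 pregnant cows.

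In all, 2798 of 11963 genes passed in mononuclear cells, 1301 higher and 1497 lower, and 1517 by more than 2-fold, and the values of the 4 and 4 animals did not overlap for 30.7% of genes against 2.86% by chance. Within slide 7, which held 3 pregnant and 4 cycling animals, 644 genes passed, and with slide as a fixed block over the 12 single arrays 1784. Against the estrous cycle 1st alone 1488 passed. The majority turned to higher with quantile normalization (1900 of 3336), over the 12 single arrays (2131 of 4056) and with the stricter filter (1400 of 2786). With quantile normalization the median of all genes shifted from 0.05 to 0.16. CDKL4, CXCL8 and DUSP1 missed the threshold within slide 7, CXCR1 and SDS with slide as a fixed block, and NUAK1 with normexp correction. The count was 1222 without pregnant array 3 and 4243 without pregnant array 2, and NUAK1 missed the threshold without pregnant array 3 (adjusted p = 0.06132).

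**Figure D4:**
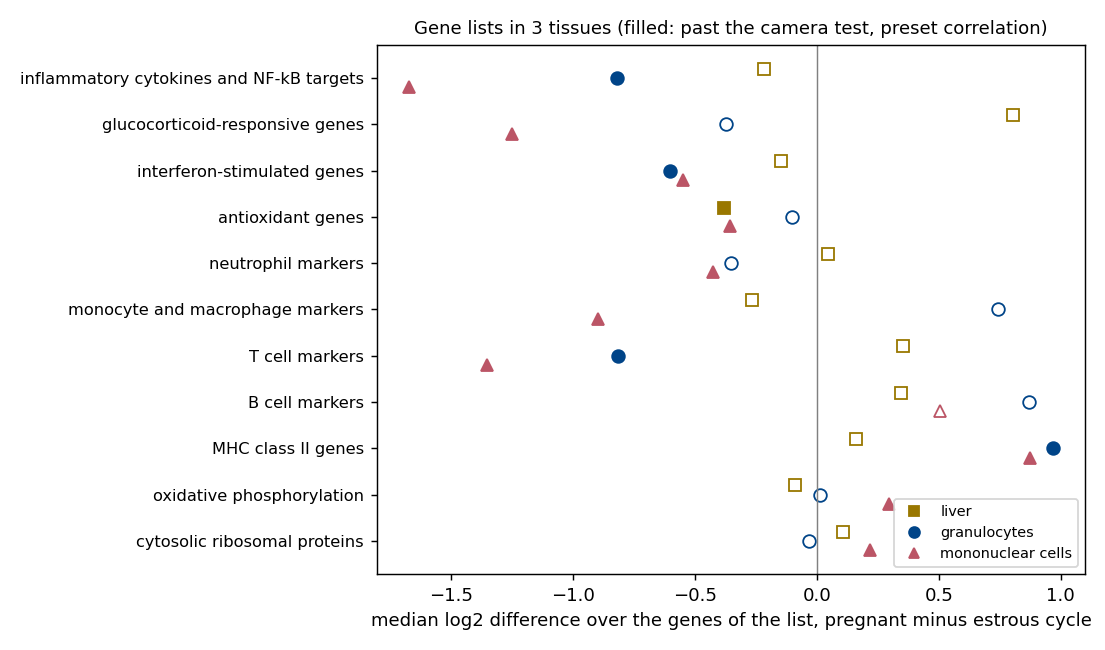
The x axis gives the median log2 difference of 11 gene lists, pregnant minus estrous cycle, the y axis the lists and the symbols the 3 tissues, filled where camera with the preset correlation passed. The inflammatory list had medians of -0.82 in granulocytes and -1.67 in mononuclear cells, and MHC class II genes had medians of 0.97 and 0.87.

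A further comparison asked whether the pregnancy changes of 1 tissue were those of another. DUSP1 rose in liver (3.21) and fell in mononuclear cells (-2.98), a difference of 6.19 ± 0.95 (adjusted p = 0.0008121). H2BC12 rose in all 3 tissues, by 1.13 in liver, 3.54 in granulocytes and 4.18 in mononuclear cells, and its rise in liver was the smaller of each pair (-2.41 ± 0.67 against granulocytes and -3.05 ± 0.80 against mononuclear cells). Its liver call was lost with normexp correction. The change differed for 1499 of 10263 genes between liver and granulocytes, for 3182 of 10592 between liver and mononuclear cells, and for 559 of 10988 between the 2 blood fractions. The changes had opposite signs for 1122, 2353 and 424 of these. With numbers as blocks the counts were 1294, 3142 and 1201. By the rule of r above 0.1 over animal values, numbers paired the 2 blood fractions in both states and liver with them in the estrous cycle only. Over single arrays of the 1st and the 2nd, neither the 2 blood fractions nor liver with granulocytes passed it. Across genes, Pearson's r of the changes was 0.246 between liver and granulocytes, 0.098 between liver and mononuclear cells and 0.469 between granulocytes and mononuclear cells, and Spearman's rho was 0.292, 0.093 and 0.488. Genes are not independent replicates, so each r was set against all 35 splits of the animals in an exact permutation test. None of these 3 relations passed (permutation p = 0.143, 0.771 and 0.343 for r, adjusted 0.429, 0.771 and 0.514, and 0.0571, 0.771 and 0.257 for rho, adjusted 0.171, 0.771 and 0.386). Since 1 of 35 is the smallest share that 35 splits can give, 1 relation alone could not have passed after adjustment over the 3. A relation between tissues is thus neither shown nor excluded. On leaving out a number, r ran from 0.217 to 0.268, from 0.046 to 0.143 and from 0.377 to 0.549.

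These interaction counts moved with single animals, and 2 of the 3 with slide. With slide as a random block, a choice made after the data were seen, 711 genes passed between liver and granulocytes, 3521 between liver and mononuclear cells and 308 between the blood fractions. Against the estrous cycle 1st alone 60 passed between the blood fractions and against the 2nd alone 1670, and without the filter 2261 passed between liver and granulocytes. For liver and granulocytes the count was 979, 907 and 798 without estrous number 1, 2 and 4 and 828 without pregnant number 3. For liver and mononuclear cells it was 1967, 1888 and 2041 without the same estrous numbers and 1894 without pregnant number 3. For the blood fractions it was 210, 173, 306 and 148 without estrous numbers 1 to 4, and 851 and 306 without pregnant numbers 2 and 3.

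The estrous cycle 2nd was compared with the 1st in each tissue, over 4 arrays each, taken to come from the same 4 cows. In granulocytes the vasoconstrictor gene EDN1 (2.73 ± 0.58), the coagulation starter F3 (2.62 ± 0.54), the transcription factor gene MAFF (2.17 ± 0.42) and CD83 (2.15 ± 0.34) were higher in the 2nd. EAF2 was 9.97-fold lower (-3.32 ± 0.41), and PRR15L and KCNK5 were at least 2.58-fold and at least 2.52-fold lower. In all, 1115 of 10841 genes passed, 114 higher and 1001 lower. The groups did not overlap for 18.4% of genes, against 2.86% by chance. Oxidative phosphorylation genes were higher in the 2nd as a list (median 0.30, adjusted p = 6.677e-06), although none of the 51 members passed alone, over all genes or adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.525). All 4 2nd arrays lay on another slide than the 1st arrays, and with slide as a random block 187 genes passed, and with numbers as blocks 644. EDN1, F3, MAFF, CD83 and PRR15L missed the threshold in the fit with slide. EDN1, F3, PRR15L and KCNK5 missed it with normexp correction. With normexp correction 485 passed and with quantile normalization 447, 98 higher and 349 lower, while the median of all genes shifted from -0.11 to 0.04. The count was 557, 463 and 526 without 2nd arrays 1, 2 and 3, and 712 and 429 without 1st arrays 3 and 4. EDN1 missed the threshold without 2nd array 2 (adjusted p = 0.0646) and 1st array 4 (adjusted p = 0.06715), and MAFF without 1st array 4 (adjusted p = 0.05117).

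In mononuclear cells the genes higher in the 2nd included EDN1 (4.52 ± 0.58), MAFF (2.59 ± 0.13, adjusted p = 0.0001979), ATF3 (2.56 ± 0.29) and F3 (at least 3.65-fold). Of 25 inflammatory cytokines and NF-kB targets 7 were higher, none lower, and 14 were higher adjusted over the list alone (median 1.09, adjusted p = 2.408e-09). This call was lost with an estimated correlation (adjusted p = 0.586). The members that were higher included CXCL8 (2.41 ± 0.39), CXCL5 (2.32 ± 0.35) and CCL3 (1.83 ± 0.15). PPIL1 was at -1.99 ± 0.24. Cell cycle genes were lower as a list, with a median of -0.50 over 18 genes (adjusted p = 4.185e-05), of which none passed over all genes and 2 adjusted over the list alone. This call was also lost with an estimated correlation (adjusted p = 0.724). In all, 105 of 11761 genes passed, 68 higher and 37 lower, and the groups did not overlap for 10.9% of genes against 2.86% by chance. With numbers as blocks 3 genes passed, and EDN1, F3, ATF3, CCL3 and PPIL1 missed the threshold.

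This count turned on single arrays. Without number 2 in both phases, a choice made after the data were seen, 1230 genes passed, 264 higher and 966 lower, and the genes named for mononuclear cells here kept their direction and stayed past the threshold. The count was 184 without 1st array 2, 390 without 2nd array 2, of which 279 were lower, 2 without 1st array 1, 4 without 1st array 3 or 4, 4 without 2nd array 1 and 3 without 2nd array 3 or 4. Of EDN1, F3, MAFF, ATF3, CXCL8, CXCL5, CCL3 and PPIL1, MAFF and CCL3 passed without any single array. The other genes missed the threshold without at least 5 of the 8 arrays, at adjusted p from 0.0501 to 0.13018. Within slide 7, with 4 arrays of the 1st and 1 of the 2nd, 4 genes passed, and with slide as a fixed block 2. With normexp correction 159 passed, with quantile normalization 164, with an intensity trend 176 and without the filter 20.

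**Figure D5:**
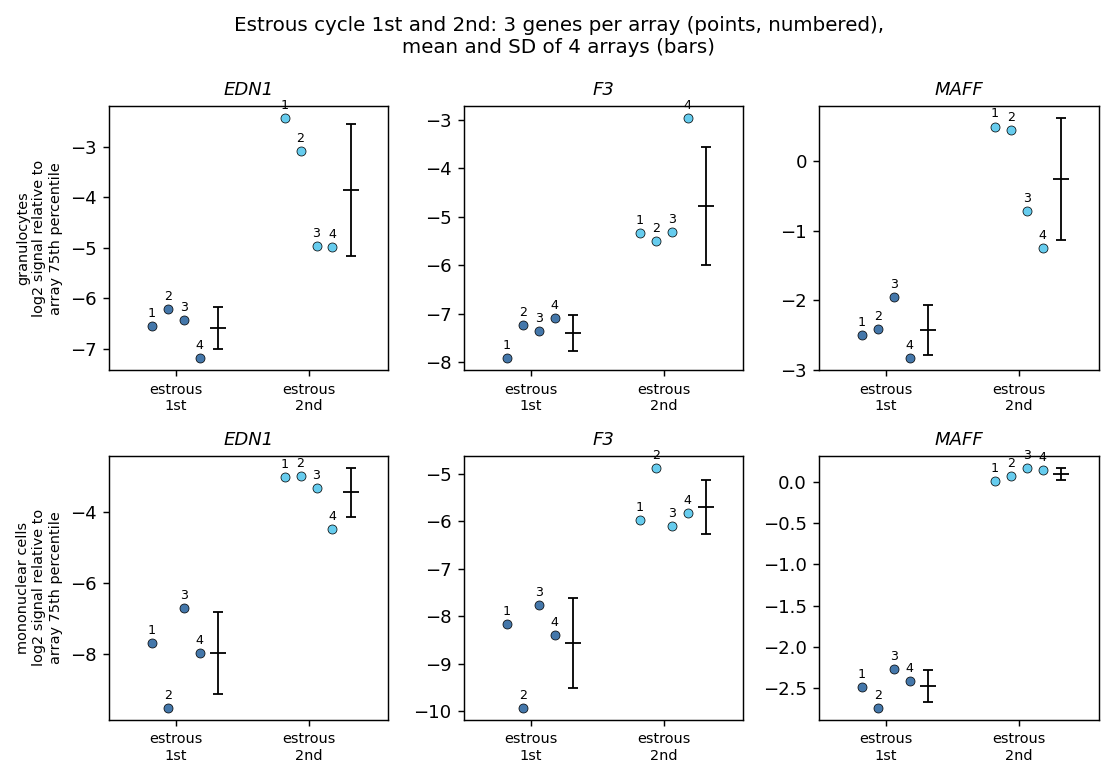
The panels plot EDN1, F3 and MAFF in granulocytes (top) and mononuclear cells (bottom), with the log2 signal relative to the array's 75th percentile on the y axis, the estrous cycle 1st and 2nd on the x axis, a point per array with its number, and the mean with SD of 4 arrays as a bar. All 3 genes lay higher in the 4 arrays of the 2nd in both fractions, by 2.17 to 2.73 in granulocytes, and in mononuclear cells by 4.52 for EDN1, 2.59 for MAFF and at least 3.65-fold for F3.

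In liver 7 of 10830 genes passed between 2nd and 1st, 5 higher and 2 lower, and 1301 had an unadjusted p under 0.05. The only named gene among them was ESPL1, separase, at least 1.95-fold higher in the 2nd. Equal numbers pair the liver arrays, and with numbers as blocks 2 genes passed. Lists moved without any member that passed: plasma transport proteins were lower in the 2nd (median -0.39, adjusted p = 4.724e-07, 0.258 with an estimated correlation, 8 of 13 lower adjusted over the list alone). Acute phase proteins were lower too (median -0.36, adjusted p = 5.58e-05, 5 of 16 lower adjusted over the list alone), and cholesterol synthesis genes were higher (median 0.47, adjusted p = 0.000151, none of 13 adjusted over the list alone). With an estimated correlation these 3 calls were lost (adjusted p = 0.523 and 0.570 for the last 2). The calls were also lost with quantile normalization for the plasma transport list (adjusted p = 0.09714) and without the filter for the acute phase list (adjusted p = 0.06278). Each group lay on a slide of its own, so the phase and the slide cannot be told apart. The count was 1889 without the filter and 4 with the stricter filter. It was 2 and 1 without 1st arrays 3 and 4, and 3, 1 and 2 without 2nd arrays 1, 2 and 4. ESPL1 missed the threshold without 1st array 3 or 4 or any 2nd array, at adjusted p from 0.06682 to 0.1715.

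Granulocytes were compared with mononuclear cells over 8 values each to show what separates the fractions. Of 14 neutrophil markers 12 were higher in granulocytes, with the same count adjusted over the list alone (median 1.65, adjusted p = 1.094e-06; adjusted p = 0.567 with an estimated correlation, where the call was lost), among them CXCR1, which was 157-fold higher (7.29 ± 0.62). Of 17 granule and antimicrobial genes 12 were higher, and 13 adjusted over the list alone (median 2.18, adjusted p = 9.394e-07; 0.567 with an estimated correlation), among them the cathelicidin gene CATHL4 (5.20 ± 0.39) and OLFM4 (4.45 ± 0.37). P2RY12 (5.24 ± 0.55), IGFBP1 (4.35 ± 0.42), FCAR (3.93 ± 0.28), IL1B (5.34 ± 0.50), SDS (6.42 ± 0.64) and DGAT2, a triglyceride synthesis enzyme (6.22 ± 0.57), were higher too. Of 51 oxidative phosphorylation genes 19 were lower and 1 higher, with the same counts adjusted over the list alone (median -0.21, adjusted p = 0.00856; 0.989 with an estimated correlation), among them NDUFS6 (-0.82 ± 0.12), and MCM5, a DNA replication gene, was at -1.41 ± 0.21. Of 13 T cell markers 3 were lower and 1 higher, and 2 lower and 1 higher adjusted over the list alone, with CD5 at -1.15 ± 0.27 and CD3G at 0.65 ± 0.19 (list adjusted p = 0.95541). Of 8 B cell markers 2 were lower and none higher. Of 11 NK and cytotoxic cell markers 2 were higher and 2 lower, and of 13 monocyte and macrophage markers 2 and 1. MHC class II genes had 1 of 11 higher and 1 lower, and none adjusted over the list alone. None of these lists passed camera. Fry called the B cell list, with 7 of 8 members lower in sign in granulocytes (adjusted p = 0.00901), and none of the others. In all, 5102 of 12103 genes passed, 2562 higher and 2540 lower, and the 8 and 8 values did not overlap for 7.25% of genes against 0.0155% by chance. Equal numbers passed the pairing rule between the fractions over animal values but not over single estrous cycle arrays. With numbers as blocks 5400 genes passed, of which 2787 were lower. No slide held both fractions but slide 6, and with slide as a random block, a choice made after the data were seen, 2398 passed and the call of CD3G was lost. With normexp correction 5229 of 7108 genes were higher and the median of all genes shifted from -0.03 to 0.23.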

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

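Arrays were set apart where 1 of the 4 values of a group lay far from the other 3 by Dixon's test, which chance does in about 1 in 20 groups. This was so in 19 of 424 groups, against 21.2 expected by chance, so the number of such arrays is that of chance. The 75th percentile of the signal of mononuclear pregnant array 1, the only mononuclear array on slide 6, was 2743, against 3989 to 4076 in the others.

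In liver, PAG7 was -6.97 in estrous cycle 1st array 3 against -8.40 to -8.21 in the others, IGFBP1 2.58 in 1st array 4 against 1.79 to 1.90, PCK1 5.76 in the same array against 5.32 to 5.39, and NFE2L2 0.82 in pregnant array 3 against 0.95 to 0.96. GADD45G was -1.67 in 2nd array 2 against -0.81 to -0.63, AHR -3.71 in 2nd array 3 against -2.57 to -2.46, and MCM7 0.70 in 2nd array 2 against 1.1 to 1.15. CD9 was -3.91 in 1st array 1 against -4.79 to -4.68, and -5.76 in pregnant array 3 against -5.18 to -5.09. In granulocytes, BOLA-DOB was -1.55 in 2nd array 4 against -0.25 to -0.00, AHR -2.53 in the same array against -1.57 to -1.45, F3 -2.96 there against -5.51 to -5.32, and METTL1 0.79 in pregnant array 2 against 1.62 to 1.72. In mononuclear cells, CXCL3 was -2.56 in 1st array 4 against -4.81 to -4.44, and BOLA-DOB 0.31 in the same array against 0.03 to 0.07 and -0.56 in 2nd array 2 against -0.03 to 0.05. In 1st array 2, CXCL8 was 1.24 against -0.15 to -0.10 and S100A12 6.21 against 6.99 to 7.11.

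The pregnancy change differed between liver and granulocytes for 1499 genes, between liver and mononuclear cells for 3182 and between the blood fractions for 559. Among 44 gene tests, the change in liver minus that in granulocytes was 1.44 for CREB3L1 (adjusted p = 0.00875), -2.41 for H2BC12 (adjusted p = 0.02583) and 1.15 for MAF (adjusted p = 0.0134). The change in liver minus that in mononuclear cells was 1.35 for CREB3L1 (adjusted p = 0.01799), 6.19 for DUSP1 (adjusted p = 0.0008121), -3.05 for H2BC12 (adjusted p = 0.01187), 2.04 for MAF (adjusted p = 0.00588) and 1.62 for NOS3 (adjusted p = 0.01249).

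Each count of genes, but not the gene list result, was set against splits of the same values into groups of the same sizes. For pregnant against estrous cycle, 1 of 35 splits gave as many genes as the real one in each tissue, the real one itself, with highest other counts of 12 against 3073 in liver, 1 against 1969 in granulocytes and 1 against 2798 in mononuclear cells. For granulocytes against mononuclear cells it was 1 of 100 drawn splits, with a highest other count of 1 against 5102, and for the interactions 1 of 35 each, with highest other counts of 1, 3 and 0 against 1499, 3182 and 559. No other split came near these counts, but 1 of 35 is the smallest share that 35 splits can give. Splits that mix the groups also put the real difference into the spread, which lowers their counts. The 100 drawn splits did not keep equal numbers paired, and the splits took no account of slide. Chance is thus made unlikely rather than excluded, and slide was not addressed. For 2nd against 1st in granulocytes it was 1 of 35, with a highest other count of 4 against 1115. If equal numbers are the same cow, only 8 splits part every number, too few for a share under 0.05, with a highest other count of 0, and 644 genes passed with numbers as blocks. For 2nd against 1st in liver it was 4 of 35, with a highest other count of 16 against 7, so chance cannot be excluded; only 8 splits part every pair, too few for a share under 0.05, and their highest other count was 0. For 2nd against 1st in mononuclear cells it was 2 of 35, with a highest other count of 641 against 105, so chance cannot be excluded. That split exchanged the 2 arrays of number 2, which points to a structure of the samples.

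Of the patterns seen, 3 are weighed below. The muscle list, the tests on T cell markers and on carried-over neutrophils, and the check of number 2 were chosen after the results were seen. A further pattern, lymphocyte genes in granulocytes, is described in the report and was not weighed.

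The lower neutrophil, granule, monocyte and platelet genes in mononuclear cells of pregnant cows had a median of -1.06 over 44 genes. Slide as the cause is argued against by the median of -0.85 within slide 7. A smaller share of neutrophils, platelets and monocytes alone would not lower T cell markers, whose median was -1.35. That median had been seen before the test was chosen, so it describes the samples and tests nothing. Neutrophils carried into the estrous cycle samples stay open. The median of -2.64 over 4 neutrophil and granule genes at least 8-fold higher in granulocytes decides nothing, since these genes belong to the lists already seen to fall and were picked with the pregnant mononuclear values.

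Some skeletal muscle genes were lower in the liver of pregnant cows, whereas ACTC1 rose by 1.35. Muscle in some estrous cycle liver samples is left undecided by 20 muscle genes not looked at before, with a median of -0.0113, of which 7 were lower past the threshold, none higher and 13 not past it. The mean of the muscle genes ranged over 2.16 log2 between the 4 estrous cycle 1st arrays, which shared a slide. Slide thus does not account for the spread among these arrays. No slide held both pregnant and cycling liver arrays, so a slide difference between the states is not addressed. Over all 26 muscle genes, those already seen included, the mean was -2.35 in estrous cycle 1st array 3. It was -1.75 in 2nd array 1 and -2.11 in 2nd array 2. In the other estrous cycle arrays it ran from -4.87 to -3.45, and in the pregnant ones from -5.12 to -4.65. The difference thus lay mostly in single arrays, which was not tested. What the source was stays open.

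Number 2 of the mononuclear cells stood apart between the phases, a pattern picked after the split counts were seen. Over the 200 genes that best separated the phases in the other numbers, its 1st array lay nearer the 2nd mean for 56%, which leaves exchanged labels undecided. Its 2nd array lay nearer the 1st mean for 67%, although it shared a slide with the other 2nd arrays but 1, which argues against slide. EDN1, MAFF and CXCL8 kept their direction in number 2. The state of the animal was not tested and stays open.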

How the results depend on the processing

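Over 14 results, 238 settings were run, of which 169 left the value within 1.5 times the first or its call unchanged and 69 did not, 30 of them other than leaving out an array. The cause was not tested for any of them. No gene list passed with an estimated correlation, 0 against 47 of 196 tests. This held even for neutrophil markers between the blood fractions, 12 of 14 higher in granulocytes (camera adjusted p = 0.567). A call lost in this setting thus does not tell whether the list moved. Of 342 settings of gene lists 304 kept the call and 38 lost it. Some lists described above passed camera but not fry. In pregnancy these were the inflammatory, interferon and T cell lists of granulocytes (fry adjusted p = 0.06788, 0.25989 and 0.10873). For 2nd against 1st they included oxidative phosphorylation in granulocytes (0.2129). The inflammatory and cell cycle lists in mononuclear cells (0.05581 and 0.20144) and acute phase and cholesterol synthesis in liver (0.12137 and 0.36478) were the others.

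For the genes named in the text, 2880 of 3014 settings kept the call and 134 lost it. These genes were partly picked for steady calls after the alternatives had been run. For 24 of the choices left out of the text, 422 of 551 kept it, 128 lost it and 1 reversed: RHNO1 in granulocytes against mononuclear cells, -1.89 first and 0.0784 with normexp correction.

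For pregnant against estrous cycle, liver gave 4838 genes without the filter against 3073, and 2147 to 3339 on leaving out an array. Granulocytes gave 733 against the 1st alone and 1227 over single arrays against 1969, and 1008 to 2669 on leaving out an array. Mononuclear cells gave 1794 with numbers as blocks, 1488 against the 1st alone, 1784 with slide as a fixed block and 644 within slide 7 against 2798, and 1222 to 4243 on leaving out an array. Blocks by number gave 2335 in liver and 1789 in granulocytes, where the numbers do not pair the animals.

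For 2nd against 1st, liver gave 1889 without the filter, 4 with the stricter filter and 2 with blocks against 7, and 1 to 9 on leaving out an array. Granulocytes gave 485 with normexp, 447 with quantile, 644 with blocks and 187 with slide as a random block against 1115, and 429 to 1367 on leaving out an array. Mononuclear cells gave 159 with normexp, 164 with quantile, 20 without the filter, 176 with a trend, 3 with blocks, 2 with slide as a fixed block and 4 within slide 7 against 105, and 2 to 390 on leaving out an array. Without number 2, added afterwards, 1230 passed and the majority turned to lower.

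Slide as a random block, added afterwards for these, gave 2398 against 5102 for granulocytes against mononuclear cells, 711 against 1499 for liver against granulocytes and 308 against 559 for the blood fractions. Liver against granulocytes gave 2261 without the filter and 798 to 1958 on leaving out a number. Liver against mononuclear cells gave 3521 with slide as a random block against 3182, and 1888 to 4043 on leaving out a number. The blood fractions gave 1201 with blocks, 60 against the 1st alone, 1670 against the 2nd alone and 148 to 851 on leaving out a number.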

Other observations

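Some genes passed in the same direction in all 3 tissues. Of 10208 genes tested in all of them, 60 were higher in pregnancy in every tissue, against 19.3 expected from the separate counts, and 44 were lower, against 9.85. By pairs, 337 were higher in both blood fractions against 118 expected, and 310 in liver and granulocytes against 167. In liver and mononuclear cells 173 were higher, fewer than the 194 expected. For lower genes these counts were 288 against 91.3, 143 against 77.0 and 171 against 141. The excess was thus largest between the 2 blood fractions. These counts were not tested, because the tissues come from the same animals. H2BC12 changed by 1.13 in liver, 3.54 in granulocytes and 4.18 in mononuclear cells, RAB30 by 0.97, 0.95 and 1.1, and METTL1 by 0.88, 1.35 and 1.49. NOS3, the endothelial nitric oxide synthase, changed by -0.86, -2.25 and -2.47, the transcription factor gene MAF by -0.68, -1.83 and -2.72, and CREB3L1 by -0.72, -2.16 and -2.07. Some of these calls did not hold throughout. H2BC12 missed the threshold in liver with normexp correction. RAB30 missed the threshold without pregnant array 3 in liver (adjusted p = 0.06093) and in mononuclear cells (adjusted p = 0.05878), METTL1 in mononuclear cells without the same array (adjusted p = 0.05818), and RAB30, NOS3 and METTL1 in granulocytes within slide 4. RAB30 and METTL1 missed it in mononuclear cells within slide 7. These 6 genes were picked after the results were seen.

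Of 3 eosinophil and basophil markers tested, 2 were lower in both blood fractions of pregnant cows, and 2 were lower and 1 higher adjusted over the list alone. ALOX15 changed by -1.80 ± 0.35 in granulocytes (adjusted p = 0.01169) and by -4.05 ± 0.69 in mononuclear cells (adjusted p = 0.00954), and CCR3 by -1.51 ± 0.35 (adjusted p = 0.02116) and -3.08 ± 0.76 (adjusted p = 0.02536). HDC did not pass over all genes, at 0.60 ± 0.20 in granulocytes (adjusted p = 0.06535) and 0.54 ± 0.23 in mononuclear cells (adjusted p = 0.11499), and is the 1 that was higher adjusted over the list alone. The list is too short for a set test. CCR3 missed the threshold without pregnant array 3 in granulocytes (adjusted p = 0.05102) and in mononuclear cells (adjusted p = 0.0713), and ALOX15 in mononuclear cells without estrous cycle 2nd array 2 (adjusted p = 0.05314). Eosinophils were not counted.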
